A study of Mus musculus with 16 samples.

How the data were processed

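Polyadenylated RNA of the nucleus accumbens of male C57BL/6 mice was measured in 16 libraries, 4 for each of 4 groups exposed for 4 days to saline, arecoline, caffeine or nicotine. Per the labels' protocols, RNA was extracted with Trizol, reverse transcribed from an oligo-dT primer with a template-switching oligonucleotide, amplified by PCR and sequenced on an Illumina NovaSeq instrument. Whether strand was kept is not given in the sources used here, so reads of overlapping genes on opposite strands were taken as assigned by the authors' counting. No molecular identifiers are mentioned in the labels, so amplified copies were counted as separate reads.

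The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM with the mm10 genome build, with no role or order given. The annotation release used for counting is not given in the sources used here. The deposited table holds 22337 gene rows with 2 columns per library, per the file headers. The first column holds estimated counts as deposited by the authors, not scaled for depth, and between 86.6% and 90.4% of them were exactly whole, with no tolerance and zeros included, or between 82.7% and 86.8% of the values above 0. The other holds FPKM values computed by the authors, which are scaled to gene length and to the library total. All columns matched a library by the sample labels, and the number of columns left unmatched was 0. Gene identifiers were matched to GENCODE M21 on the same build, which gave a symbol and coordinates for 22232 of them and left 105 unmatched. Symbols in the text come from that release.

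The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. The filterByExpr filter kept 14674 genes, TMM factors scaled the libraries, and a quasi-likelihood model with a mean for each group was fitted to all 16 libraries. Each compound was compared with saline and with each other compound in 6 contrasts, and an F test asked for any difference among the 4 groups. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05 and no minimum fold. Levels are given as TMM-scaled CPM (counts divided by the scaled library total in M) with the SD over libraries, and log2 fold changes with their standard error from the model. A design with FPKM and limma had been written for the case that the table held no counts. Since it held counts, the FPKM test became an alternative, as that design provided.

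Gene lists were fixed before the data were examined, 23 of them for functions and 21 for cell types. Of their 775 distinct genes, 771 were in the table. Each list was tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, with adjustment over the 44 lists of a contrast. The same test with a correlation estimated from the data stood beside it. So did fry, which tests a list against no change, whereas camera ranks its genes against the others. A list score was computed for each library as the mean over members of log2 CPM centred on the mean of all libraries, and scores were compared with saline by exact permutation tests, for which 0.0286 is the smallest two-sided p that 4 against 4 libraries allow. Fold changes of the compounds share the saline libraries, so their correlation was set beside that of 1000 simulations of unchanged groups. In each, the libraries' deviations from their group means were shuffled over the groups, and the compound groups shared a control group drawn in this way.

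Genes named in the text followed a rule written before the data were examined. Against saline, it took the 10 largest changes in each direction among named genes past the threshold with all 4 compound libraries on 1 side of the saline mean. Where fewer than 5 genes passed in all, it took the 5 with the smallest p in each direction. It added 14 genes whatever their test, among them receptors for dopamine, acetylcholine and adenosine, and up to 4 members of each list past its threshold. Between compounds it took 5 genes in each direction. Members of near-identical families (Hspa1a with Hspa1b, the haemoglobin genes, ribosomal protein genes with their pseudogenes) share reads, and their counts depend on how the authors' software divided those reads.

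Total estimated counts ran from 9.04 to 24.32 M per library with a median of 14.94 M. At the lowest total, 1 CPM corresponds to 9.04 counts, so values under 1 CPM rest on few reads. No pair of libraries within a group agreed within sampling noise, since the lowest chi-square per degree of freedom was 12.0, and none was treated as a duplicate.

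The steps were tested on simulated data made for the caffeine and saline comparison with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. There edgeR recovered 28.4% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 89.4% of those changed 4-fold, with 4 false calls among 125. DESeq2 1.42.0 recovered 44.8%, 79.1% and 90.9% with 17 false calls among 160. Simulated genes varied independently of each other, so these rates do not cover variation that genes share between the real libraries. Alternatives comprised DESeq2, other scalings and filters, FPKM values with limma at pseudocounts of 1 and 0.1, quality weights, the replicate number as a block, and the removal of each library in turn. Alternatives added after the data were seen comprised a score of medium spiny neuron genes as a covariate, the removal of 4 libraries, thinning to the lowest total, and the removal of trends with transcript length, GC content and gene span. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.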

Results

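RNA of the nucleus accumbens, the part of the ventral striatum in which dopamine input shapes reward learning, was sequenced from male mice of the C57BL/6 strain after 4 days of exposure to saline or to a plant alkaloid. Arecoline, from the areca nut, activates muscarinic acetylcholine receptors, caffeine blocks adenosine receptors, and nicotine activates nicotinic acetylcholine receptors. Each of the 4 groups held 4 libraries. Doses and routes are not given in the sources used here, and no label says that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical. The total estimated count per library was 13.8 ± 1.29 M for saline, 16.6 ± 2.12 M for arecoline, 19.5 ± 4.74 M for caffeine and 13.5 ± 3.22 M for nicotine (SD, n = 4 each). Mitochondrially encoded genes took 5.47 ± 0.83% of the counts with saline, 4.09 ± 0.47% with arecoline, 4.08 ± 0.34% with caffeine and 4.72 ± 0.54% with nicotine (SD, n = 4).

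Genes of striatal neurons differed widely between libraries of the same group. Drd1, the dopamine receptor of direct-pathway medium spiny neurons (mm10 chromosome 13, 54051183 to 54055705), stood at 306 CPM in saline replicate 3 and between 71.9 and 82.5 CPM in the other saline libraries. In the arecoline group it stood at 194 and 289 CPM in replicates 2 and 3 but at 9.66 and 13.7 CPM in replicates 1 and 4. It lay between 7.89 and 45.6 CPM with caffeine and between 14.3 and 27.7 CPM with nicotine. Adora2a, the adenosine receptor of indirect-pathway medium spiny neurons, and Chat, the acetylcholine-synthesising enzyme of cholinergic interneurons, had their highest levels in the same 3 libraries. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, was lowest in saline replicate 3 at 56.7 CPM and lay between 371 and 493 CPM with caffeine. Omp, which marks olfactory sensory neurons, reached 337 CPM in nicotine replicate 2 and at most 27.7 CPM in any other library. That level was in caffeine replicate 1, followed by 14.2 CPM in caffeine replicate 2 and 12.6 CPM in arecoline replicate 2, against 0.25 CPM in nicotine replicate 3. The first principal component of the log2 CPM values held 25.9% of the variance and had striatal genes such as Adora2a, Drd2 and Chat at 1 end. Saline replicate 3 and arecoline replicates 2 and 3 lay at that end, and nicotine replicate 2 stood apart on the next component, which held 17.9%.

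**Figure D1:**
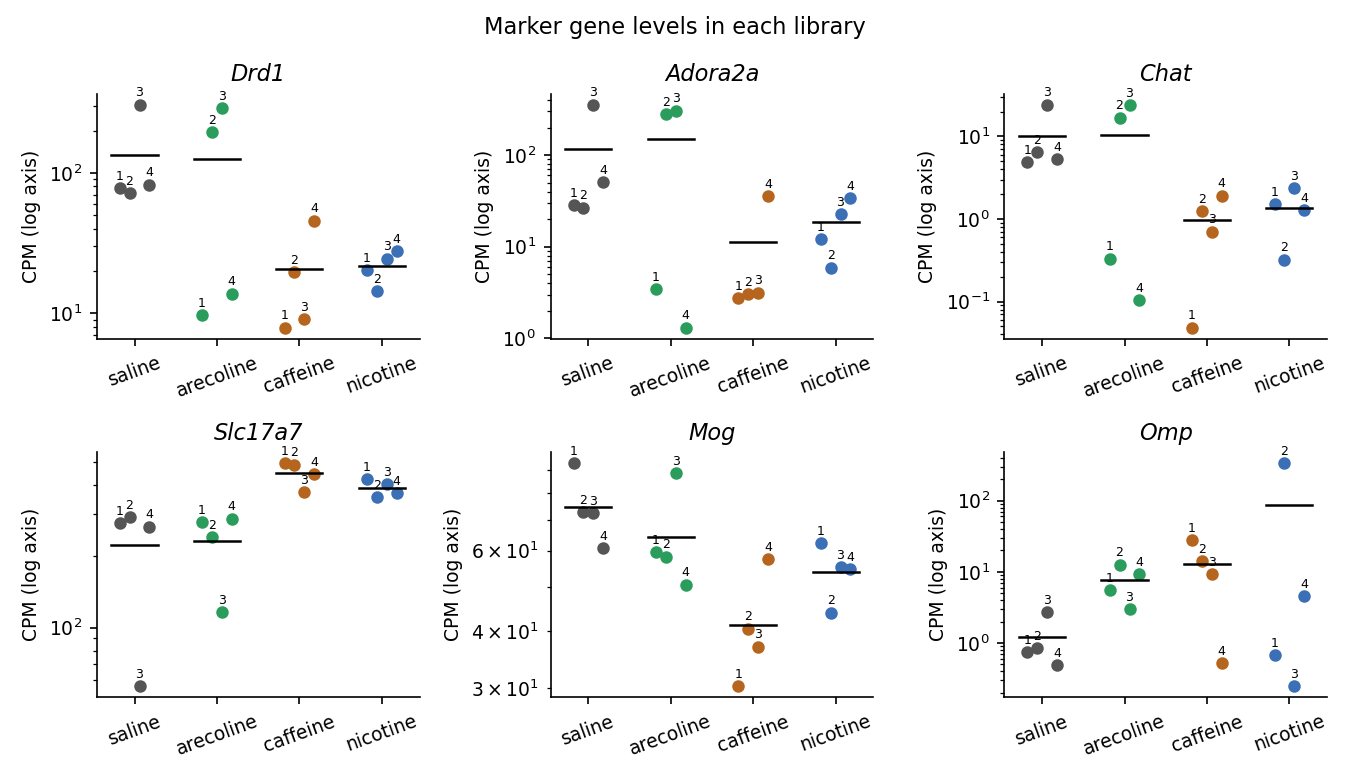
Level of 6 marker genes in each library, in CPM on a log axis, by group. Points are libraries with their replicate number and bars are group means of 4. Drd1 ran from 71.9 to 306 CPM within the saline group and from 9.66 to 289 CPM within the arecoline group, and Omp stood at 337 CPM in nicotine replicate 2.

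Caffeine was compared with saline to ask how an adenosine receptor antagonist alters transcript levels in this region. Of the genes on fixed lists, 9 of 16 oligodendrocyte and 5 of 15 astrocyte genes fell, and 5 of 20 chaperone, 3 of 29 synaptic vesicle and 3 of 24 immediate early genes rose, each past the threshold over all genes. With an estimated correlation none of these 5 lists passed as a group (adjusted p from 0.422 to 0.518). Transferrin (Trf, chromosome 9, 103204001 to 103230444), an iron carrier that oligodendrocytes make, fell from 325 ± 41.6 CPM to 171 ± 29.0 CPM (SD, n = 4), a log2 fold change of -0.93 ± 0.16 (SE; edgeR, adjusted p = 0.012). Hspa1a (chromosome 17, 34969190 to 34972156), the inducible 70-kDa class chaperone, rose from 16.8 ± 3.87 to 42.4 ± 5.57 CPM, a log2 fold change of 1.34 ± 0.22 (adjusted p = 0.011). Of the 14674 genes tested, 293 were higher and 306 lower at an adjusted p under 0.05. Of those 599 genes, 356 differed by at least 1.5-fold and 123 by at least 2-fold.

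Oligodendrocyte genes ranked lower with caffeine. Their median log2 fold change was -0.83 over 16 measured genes, with 9 past the threshold over all genes and 16 when adjusted over the list alone (camera, adjusted p = 4.1e-15). With an estimated correlation the adjusted p was 0.422. Against no change, which is not a test of rank, fry gave an adjusted p of 0.025. Trf was joined by Aspa, which breaks down N-acetylaspartate (log2 fold change -1.10 ± 0.22), by the connexin gene Gjc3 (-0.90 ± 0.20) and by the myelin enzyme gene Cnp (-0.82 ± 0.19). Astrocyte genes were also lower, with a median log2 fold change of -0.50 over 15 genes, 5 of them past the threshold and 11 when adjusted over the list alone (camera, adjusted p = 5.2e-08; with an estimated correlation, adjusted p = 0.422). Among them Ntsr2, a neurotensin receptor, fell by 0.71 ± 0.14 on the log2 scale, the folate enzyme gene Aldh1l1 by 0.62 ± 0.15, the lipid receptor gene S1pr1 by 0.58 ± 0.12 and the acyl-CoA synthetase gene Acsbg1 by 0.67 ± 0.17. Alongside both glial lists, the pan medium spiny neuron list had a median log2 fold change of -1.72.

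Chaperone genes ranked higher with caffeine. The heat shock and unfolded protein response list had a median log2 fold change of 0.29 over 20 genes, with 5 genes higher over all genes and 10 when adjusted over the list alone (camera, adjusted p = 4.8e-08). Its adjusted p was 0.422 with an estimated correlation, and 0.0034 with fry, which tests against no change and not for rank. Dnajb1, a co-chaperone of heat shock proteins (chromosome 8, 83608193 to 83612653), rose from 66.9 ± 0.82 to 106 ± 5.55 CPM with an adjusted p of 0.0037, the lowest value in this comparison and shared with H2afx and Pcdh11x. Sdf2l1, of the endoplasmic reticulum, rose by 0.78 ± 0.11 on the log2 scale (adjusted p = 0.0067). Both passed in all 24 alternatives that gave them a value, as did Hspa1a. Cytosolic ribosomal protein genes were higher in 50 of 50 cases by a median of 1.19-fold, with 0 genes past the threshold over all genes or over the list alone (camera, adjusted p = 1.8e-08; with an estimated correlation, adjusted p = 0.536). Their list score had an exact permutation p of 0.143 against saline. Over all genes, log2 fold changes against saline fell weakly with transcript length. The Spearman correlations were -0.138, -0.133 and -0.132 for arecoline, caffeine and nicotine, and their part in list ranks was not tested. Nuclear-encoded respiratory chain genes had a median of 1.11-fold, again with 0 of 70 past the threshold on either count (camera, adjusted p = 0.0021; with an estimated correlation, adjusted p = 0.713). Mitochondrially encoded genes had a median log2 fold change of -0.33, with 1 of 13 lower and 5 when adjusted over the list alone (camera, adjusted p = 0.0040; with an estimated correlation, adjusted p = 0.536). The gene lowered was mt-Co1, from 11158 ± 1633 to 7760 ± 566 CPM (adjusted p = 0.029), with a log2 fold change of -0.52. On FPKM with limma this was -0.54, and -0.09 with quantile normalisation added, which sets the most abundant genes to near the same values in each library.

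Genes that neurons induce when active ranked higher with caffeine. Of 24 immediate early genes, 3 passed over all genes and 9 when adjusted over the list alone, with a median log2 fold change of 0.35 (camera, adjusted p = 0.00021; with an estimated correlation, adjusted p = 0.422). Those 3 were Jun (log2 fold change 0.81 ± 0.17), Nr4a3 (0.91 ± 0.23) and Egr3 (0.51 ± 0.13), all transcription factors. Of the alternatives that gave them a value, Jun passed in 20 of 24, Nr4a3 in 13 of 23 and Egr3 in 10 of 24. Fos and Arc, at 0.69 ± 0.26 and 0.70 ± 0.31, did not pass (adjusted p = 0.121 and 0.175). Of 29 synaptic vesicle genes, 3 rose over all genes, and 10 rose and 3 fell when adjusted over the list alone (camera, adjusted p = 0.0081; with an estimated correlation, adjusted p = 0.518). Syn1, which tethers vesicles, rose by 0.70 ± 0.14 on the log2 scale, and the fusion gene Vamp2 by 0.43 ± 0.10. The muscarinic receptor gene Chrm1 (chromosome 19, 8663789 to 8683587) rose from 233 ± 32.3 to 318 ± 34.9 CPM (adjusted p = 0.029) and passed in 15 of 24 alternatives. The adenosine receptor genes did not pass, Adora1 at a log2 fold change of -0.06 ± 0.16 and Adora2a at -3.36 ± 1.39 (adjusted p = 0.837 and 0.150). The list of adenosine receptors and metabolism had a median of -0.24 with 0 of 15 past the threshold on either count (camera, adjusted p = 0.033; with an estimated correlation, adjusted p = 0.518).

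Striatal neuron lists ranked lower with caffeine although no member passed the threshold over all genes. The median log2 fold change was -1.05 over 22 dopamine signalling genes, -2.21 over 9 direct-pathway genes, -1.72 over 12 pan medium spiny neuron genes and -2.30 over 9 cholinergic interneuron genes (camera, adjusted p = 0.00012, 0.011, 0.0036 and 0.0011). With an estimated correlation the adjusted p was 0.518 for the dopamine, direct-pathway and cholinergic lists and 0.565 for the pan medium spiny neuron list. Adjusted over the list alone, 0, 5, 4 and 6 genes were lower. Drd1 stood at 20.6 ± 17.5 CPM against 135 ± 115 CPM with saline, Drd2 at 2.35 ± 2.87 against 20.2 ± 25.6 CPM, and Chat at 0.98 ± 0.79 against 10.2 ± 9.40 CPM (edgeR, adjusted p = 0.085, 0.137 and 0.098). The striatal peptide genes Penk, Pdyn and Tac1 had log2 fold changes of -1.69 ± 0.76, -2.58 ± 0.95 and -2.21 ± 0.71 and did not pass. Rgs9 and Pde10a, which end G-protein and cyclic nucleotide signals, were at -2.27 ± 0.72 and -2.61 ± 0.88 and did not pass. Cortical excitatory neuron genes had a median of 0.57 over 15 genes, with 0 past the threshold over all genes and 3 higher and 1 lower when adjusted over the list alone (camera, adjusted p = 0.0081; with an estimated correlation, adjusted p = 0.536). Without saline replicate 3 the medians of the pan medium spiny neuron and cortical lists moved to -0.73 and 0.32, and neither list passed. Genes for GABA synthesis and receptors had a median of -0.27, and other striatal interneuron genes a median of 0.53 (camera, adjusted p = 0.047 and 0.016; with an estimated correlation, adjusted p = 0.442 and 0.422). Adjusted over the list alone, 1 gene of the former was higher and 3 were lower, and 0 of the latter passed, as 0 of either did over all genes.

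Vascular, immune and blood genes ranked lower with caffeine as well. The median log2 fold change was -0.46 for 14 endothelial genes, -0.75 for 12 pericyte and smooth muscle genes, -1.42 for 12 fibroblast and meningeal genes and -0.38 for 27 extracellular matrix genes (camera, adjusted p = 0.020, 0.0081, 0.0033 and 0.0054). It was -0.21 for 16 microglial genes, -1.08 for 12 perivascular macrophage and leukocyte genes and -0.72 for 21 interferon response genes (adjusted p = 0.018, 0.022 and 0.0081). In these 7 lists 0 genes passed the threshold, both over all genes and adjusted over the list alone, and the adjusted p with an estimated correlation ran from 0.536 to 0.605. The fibroblast and meningeal score was uneven within saline, at 1.33, 0.57 and 1.69 in replicates 1 to 3 but -0.26 in replicate 4. It ran from -1.54 to 0.15 with caffeine and from -1.24 to 0.22 with arecoline. The 6 red blood cell genes had a median of -1.34, with 1 gene lower and 1 higher over all genes, and Hbb-bt, a beta-globin, fell by 1.68 ± 0.45 on the log2 scale (camera, adjusted p = 0.022; with an estimated correlation, adjusted p = 0.536). Adjusted over the list alone, 4 of the 6 were lower and 1 was higher. Hbb-bt passed over all genes in 12 of 24 alternatives.

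The largest increases among named genes past the threshold were in Psrc1 (log2 fold change 2.01), the death receptor gene Tnfrsf25 (1.93), Olfm4 (1.65), Dcaf12l2 (1.40), Hspa1a (1.34), the potassium channel subunit gene Kcng1 (2.47-fold), Cfap45 (1.29), Chrd (1.27), Hrk (1.19) and the kinase gene Dyrk3 (1.19). Chrd, which encodes the BMP antagonist chordin, rose from 20.0 ± 5.97 to 48.2 ± 5.38 CPM, and Hrk, a pro-apoptotic member of the BCL2 family, from 15.7 ± 3.30 to 35.8 ± 3.34 CPM (SD, n = 4). The largest decreases were in the troponin genes Tnni3 (-4.15) and Tnnt1 (-2.98), Rpe65 (-2.89), Tex47 (-2.35), Lrtm1 (-2.25), Zpbp (-2.16), the arginase gene Arg2 (-2.12), the serotonin receptor gene Htr4 (-2.04), Cyp2j12 (-2.04) and the neurotensin gene Nts (-2.03). Nts fell from 22.5 ± 6.00 to 5.55 ± 1.39 CPM and Htr4 from 9.99 ± 3.06 to 2.44 ± 0.71 CPM, whereas Tnni3, Tnnt1, Rpe65, Tex47, Zpbp and Cyp2j12 were under 1 CPM with caffeine. Hrk passed in all 24 alternatives, but Arg2 and Cfap45 passed in 10 of the 23 that gave them a value and Zpbp in 5 of 17. Tnni3 reached 11.2 CPM in saline replicate 2 and lay between 0.89 and 1.98 CPM in the other saline libraries. Arecoline replicates 2 and 3 had high striatal levels. Against them, arecoline replicates 1 and 4 were shifted in the caffeine direction for several of the genes listed. Psrc1 stood at 7.68, 1.92, 1.26 and 9.35 CPM in arecoline replicates 1 to 4. Nts stood at 4.76, 24.04, 23.22 and 4.39 CPM there. Tnfrsf25, Dcaf12l2, Tnnt1, Tex47 and Cyp2j12 did not split this way, and Tnni3 split the opposite way. A difference in the tissue sampled was not excluded for the genes that split. Single libraries set much of the count of 599, which became 23 without caffeine replicate 1, 49 without caffeine replicate 2, 57 without saline replicate 2, 350 without saline replicate 3 and 995 without saline replicate 1. It was 1489 with DESeq2 and, in alternatives chosen after seeing the data, 126 with the medium spiny neuron score as a covariate and 1491 without the 4 libraries that stood apart (saline replicate 3, arecoline replicates 2 and 3, nicotine replicate 2), 562 of them shared.

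**Figure D2:**
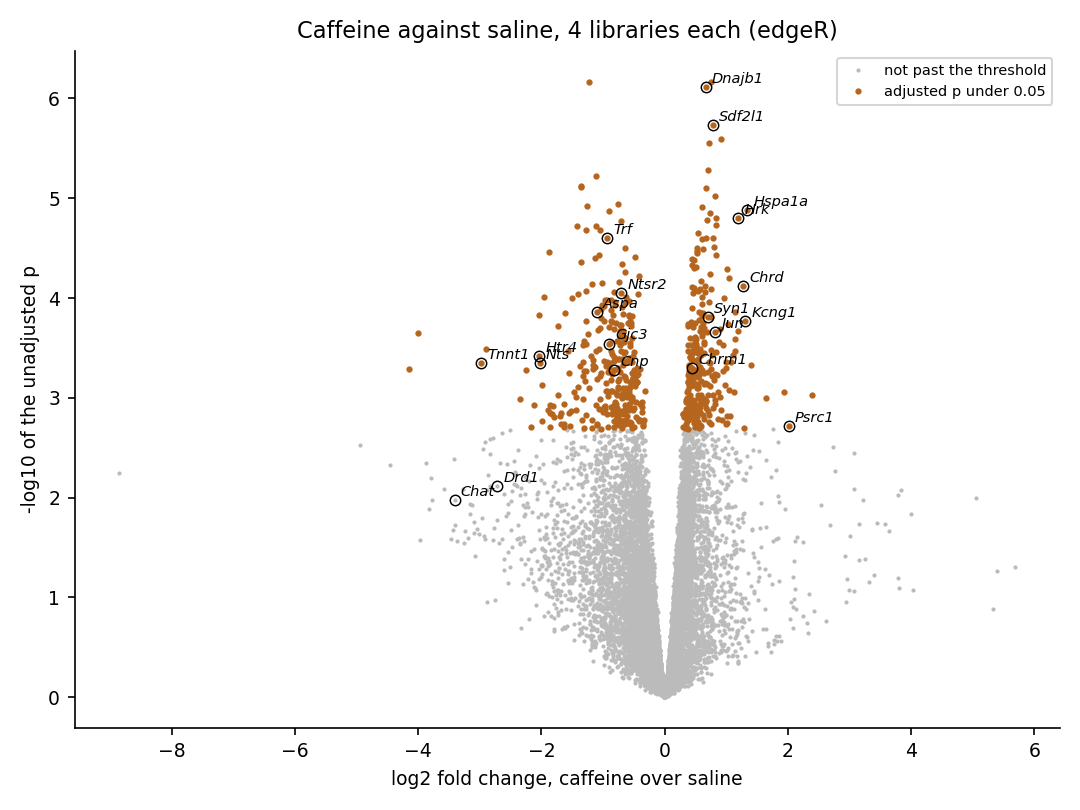
Log2 fold change of each tested gene, caffeine over saline with 4 libraries each, against the negative log10 of its unadjusted p from edgeR. Coloured points are the 599 genes past an adjusted p of 0.05, 293 higher and 306 lower, and circles mark named genes, of which Drd1 and Chat did not pass.

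Arecoline was compared with saline to ask how a muscarinic agonist alters transcript levels in the same region. H2afx and Rsrp1 were the genes past the threshold, and both were higher. H2afx (identifier ENSMUSG00000049932, chromosome 9, 44334694 to 44336077), which encodes the histone variant phosphorylated at DNA breaks, rose from 45.5 ± 4.74 to 72.3 ± 5.78 CPM (SD, n = 4), a log2 fold change of 0.67 ± 0.10 (SE; edgeR, adjusted p = 0.039). Rsrp1 (identifier ENSMUSG00000037266, chromosome 4, 134923592 to 134927671) rose from 188 ± 11.4 to 305 ± 23.0 CPM, a log2 fold change of 0.70 ± 0.11 with the same adjusted p. With 2 genes higher and 0 lower by edgeR, 2301 genes had an unadjusted p under 0.05, DESeq2 called 450 and limma on FPKM called 3.

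Chaperone genes were the group with the lowest p with arecoline, although no member passed the threshold over all genes. The heat shock and unfolded protein response list had a median log2 fold change of 0.33 over 20 genes, 19 of them above 0, and 10 passed when adjusted over the list alone (camera, adjusted p = 1.1e-08). With an estimated correlation its adjusted p was 0.380, and with fry, which tests against no change and not for rank, 0.011. Hspa5, the main chaperone of the endoplasmic reticulum, was at 417 ± 42.1 CPM against 268 ± 23.7 CPM (log2 fold change 0.64 ± 0.12, adjusted p = 0.064). Sdf2l1, Manf and Dnajb1 were at 0.55 ± 0.11, 0.57 ± 0.14 and 0.40 ± 0.09 and did not pass. Of 24 immediate early genes, 0 passed over all genes, and 7 were higher and 1 lower when adjusted over the list alone, with a median of 0.36 (camera, adjusted p = 0.0020; with an estimated correlation, adjusted p = 0.527). Fos and Arc were at 0.74 ± 0.26 and 0.88 ± 0.31, Junb at 0.82 ± 0.26 and Egr4 at -1.56 ± 0.47, and none passed. Neuropeptide genes had a median of 0.32 over 17 genes, with 0 past the threshold over all genes and 2 higher adjusted over the list alone (camera, adjusted p = 0.022; with an estimated correlation, adjusted p = 0.527). Grp, among them, was at 2.99 ± 0.91, with levels of 6.15 and 5.02 CPM in replicates 1 and 4 and of 0.45 and 0.20 CPM in replicates 2 and 3. Cytosolic ribosomal protein and nuclear-encoded respiratory chain genes had medians of 1.11-fold and 1.07-fold, with 0 genes past the threshold on either count (camera, adjusted p = 6.4e-05 and 0.0020; with an estimated correlation, adjusted p = 0.844 for both).

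Genes of immature neurons also ranked higher with arecoline. The median log2 fold change was 1.15 over 11 neuroblast genes, with 0 past the threshold over all genes and 6 higher when adjusted over the list alone (camera, adjusted p = 8.6e-06; with an estimated correlation, adjusted p = 0.527). Sox11 was at 70.1 ± 21.4 CPM against 31.2 ± 12.2 CPM and Dlx2 at 34.3 ± 16.4 against 12.6 ± 6.06 CPM (adjusted p = 0.079 and 0.086). The list score was 1.59 and 1.04 in arecoline replicates 1 and 4 but -0.50 and -0.05 in replicates 2 and 3, with an exact permutation p of 0.2 against saline, and without replicate 1 the median was 0.54. All 4 measured genes of olfactory bulb projection neurons had their highest levels of all libraries in arecoline replicate 1. Doc2g, Cdhr1, Tbx21 and Eomes stood there at 145, 89.3, 5.21 and 4.67 CPM by plain library total. Whether olfactory bulb tissue in that sample contributes to the neuroblast ranks was not tested. Astrocyte and mitochondrially encoded genes ranked lower, with medians of -0.40 each and 5 of 15 and 7 of 13 genes lower when adjusted over the list alone, against 0 over all genes (camera, adjusted p = 6.9e-06 and 1.5e-06; with an estimated correlation, adjusted p = 0.527 for both). Slc1a2, the main glutamate transporter of astrocytes, was at -0.51 ± 0.14 and mt-Co1 at -0.61 ± 0.12 on the log2 scale, and neither passed (adjusted p = 0.108 and 0.064). On FPKM with limma the value of mt-Co1 was -0.60, and -0.09 with quantile normalisation added.

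Oligodendrocyte and precursor genes had medians of -0.19 and -0.27, with 0 genes past the threshold on either count (camera, adjusted p = 0.026 and 0.018; with an estimated correlation, adjusted p = 0.844 and 0.527). Of the 18 lists that passed with arecoline, 12 still did so without arecoline replicate 1, 11 without arecoline replicate 4 and 9 without saline replicate 3. Those lost without saline replicate 3 were the neuropeptide, voltage-gated channel, ribosomal protein, nuclear-encoded respiratory chain, extracellular matrix, oligodendrocyte, endothelial, pericyte and red blood cell lists. Genes of fibroblasts and meninges, pericytes and smooth muscle, endothelium, microglia, extracellular matrix, leukocytes and red blood cells ranked lower too, with median log2 fold changes of -1.29, -0.64, -0.32, -0.20, -0.31, -0.91 and -1.08 (camera, adjusted p from 0.00038 to 0.020; with an estimated correlation, adjusted p from 0.720 to 0.844). Over all genes 0 members passed. Adjusted over the list alone, 3 microglial, 2 leukocyte and 4 red blood cell genes were lower and 1 red blood cell gene was higher, with 0 in the other 4 lists. The neutrophil gene S100a8 was at 0.53 ± 0.40 against 6.70 ± 5.22 CPM, the microglial genes Tyrobp and Cx3cr1 at -0.57 ± 0.17 and -0.36 ± 0.11, and none of them passed. Voltage-gated ion channel genes had a median of -0.15 with 0 of 30 past the threshold on either count (camera, adjusted p = 0.026; with an estimated correlation, adjusted p = 0.753).

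The remaining genes with the smallest p with arecoline, none past the threshold, were the actin-bundling gene Fscn1 (log2 fold change 0.59 ± 0.10) and F8a (0.50 ± 0.09) on the higher side. On the lower side they were Prr18 (-2.15 ± 0.37), the chloride channel gene Clcn2 (-0.98 ± 0.17), Cramp1l (-0.83 ± 0.15), Zfp106 (-0.72 ± 0.13) and the adhesion gene Ncam2 (-0.63 ± 0.11), with adjusted p of 0.061 to 0.064. Neither Chrm1 (0.04 ± 0.10) nor Chrm4 (0.37 ± 0.42) passed. Arecoline replicates 2 and 3 had the high striatal levels given above, and Drd1, at 127 ± 138 CPM against 135 ± 115 CPM, had a log2 fold change of -0.09 ± 0.83. The count of 2 became 0 without saline replicate 2, arecoline replicate 1 or arecoline replicate 3, 1 without saline replicate 1, 11 without saline replicate 3, 67 without saline replicate 4 and 198 without arecoline replicate 2. It was 99 with the medium spiny neuron score as a covariate and 952 without the 4 libraries that stood apart, with both genes in each count, and quantile normalisation of FPKM called 1 higher and 1 lower.

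Nicotine was compared with saline to ask how a nicotinic agonist alters transcript levels there, and no gene passed the threshold. By edgeR 0 genes were called, 1796 had an unadjusted p under 0.05 and the smallest adjusted p was 0.086, while DESeq2 called 104 and limma on FPKM called 0. The genes nearest the threshold on the higher side were Rtn4rl1, of the Nogo receptor family (65.8 ± 6.58 to 103 ± 5.11 CPM, log2 fold change 0.65 ± 0.10), the transcription factor gene Klf13 (0.70 ± 0.13), the kinase gene Camkk1 (0.58 ± 0.10), Ddn (0.55 ± 0.10) and Tacc1 (0.49 ± 0.09). On the lower side they were the adhesion gene Cdh18 (-1.57 ± 0.24), the kinetochore gene Nuf2 (-1.97 ± 0.38), the netrin receptor gene Dcc (-1.09 ± 0.21), Lrp1b (-1.11 ± 0.20) and Ccser1 (-1.07 ± 0.21). The nicotinic receptor subunit genes Chrna4 and Chrnb2 were at 0.45 ± 0.22 and -0.16 ± 0.12 and did not pass.

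Oligodendrocyte genes ranked lower with nicotine, with a median log2 fold change of -0.56 over 16 genes, all below 0. Over all genes 0 passed and adjusted over the list alone 13 were lower (camera, adjusted p = 4.1e-14; with an estimated correlation, adjusted p = 0.441). Trf was at 200 ± 11.2 against 325 ± 41.6 CPM, and Mbp, the myelin basic protein gene, at 2488 ± 579 against 3978 ± 315 CPM (SD, n = 4; adjusted p = 0.164 and 0.239). Striatal lists ranked lower alongside, with medians of -1.03 for dopamine signalling, -1.46 for pan medium spiny neurons, -2.06 and -1.32 for direct-pathway and indirect-pathway neurons, -2.10 for cholinergic interneurons and -1.66 for the septal or ventral forebrain neighbour list (camera, adjusted p from 3.8e-06 to 0.017; with an estimated correlation, adjusted p = 0.441 for each). In these 6 lists 0 genes passed over all genes, and adjusted over the list alone 3 direct-pathway genes were lower and 0 in the others. On FPKM with limma the septal median was 0.23, the opposite direction. Drd1 was at 21.7 ± 5.76 against 135 ± 115 CPM (log2 fold change -2.63 ± 0.89), Tac1 at -2.06 ± 0.71, Adora2a at -2.61 ± 1.34 and Chat at -2.86 ± 1.15, and none passed. Cortical excitatory neuron genes ranked higher with a median of 0.74 over 15 genes and 0 past the threshold on either count (camera, adjusted p = 0.00010; with an estimated correlation, adjusted p = 0.441). Slc17a7 was at 386 ± 30.2 against 222 ± 111 CPM and Lamp5 at a log2 fold change of 0.74 ± 0.23, and neither passed. Without saline replicate 3 the medians were 0.41 for cortical, -0.57 for pan medium spiny, -0.42 for dopamine signalling and -1.27 for cholinergic genes, and the indirect-pathway list no longer passed, at -0.40.

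Several smaller shifts accompanied these with nicotine, and 0 of their members passed over all genes. Astrocyte genes had a median of -0.25 with 1 lower when adjusted over the list alone, and mitochondrially encoded genes a median of -0.15 with 0 (camera, adjusted p = 0.00041 and 0.0497; with an estimated correlation, adjusted p = 0.441 and 0.774). Chaperone genes had a median of 0.13 and synaptic vesicle genes one of 0.13 as well, with 3 higher in the former and 6 higher and 2 lower in the latter when adjusted over the list alone (camera, adjusted p = 0.0052 and 0.014; with an estimated correlation, adjusted p = 0.441 for both). Hspa1a, Dnajb1 and Sdf2l1 were at 0.86 ± 0.22, 0.41 ± 0.09 and 0.44 ± 0.11, Syn1 at 0.51 ± 0.14, and none passed. Immediate early genes had a median of 0.19 with 2 higher when adjusted over the list alone, glucocorticoid response genes one of 0.19 with 0, and MAPK and calcium-cAMP signalling genes one of 0.09 with 2 higher and 1 lower (camera, adjusted p = 0.025, 0.019 and 0.0497; with an estimated correlation, adjusted p = 0.471, 0.441 and 0.441). Egr3 and Homer1 were at 0.54 ± 0.13 and 0.43 ± 0.12, Fkbp5 at 0.64 ± 0.23, Adcy9 at 0.64 ± 0.15 and Camkk2 at 0.41 ± 0.12, and none passed. Adenosine-related genes had a median of -0.14 with 1 lower when adjusted over the list alone, and red blood cell genes one of 0.55 with 0 (camera, adjusted p = 0.0497 and 0.025; with an estimated correlation, adjusted p = 0.441 and 0.471). Nicotine replicate 2 had the lowest depth, 9.04 M, and the Omp level given above. The count of 0 genes became 4 without saline replicate 1, stayed at 0 without any other library of the 2 groups, and became 48 without the 4 libraries that stood apart. Of the 17 lists that passed, 14 still did so with DESeq2 size factors, with the replicate block or on FPKM with limma, and those of mitochondrially encoded and MAPK genes were lost in each.

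**Figure D3:**
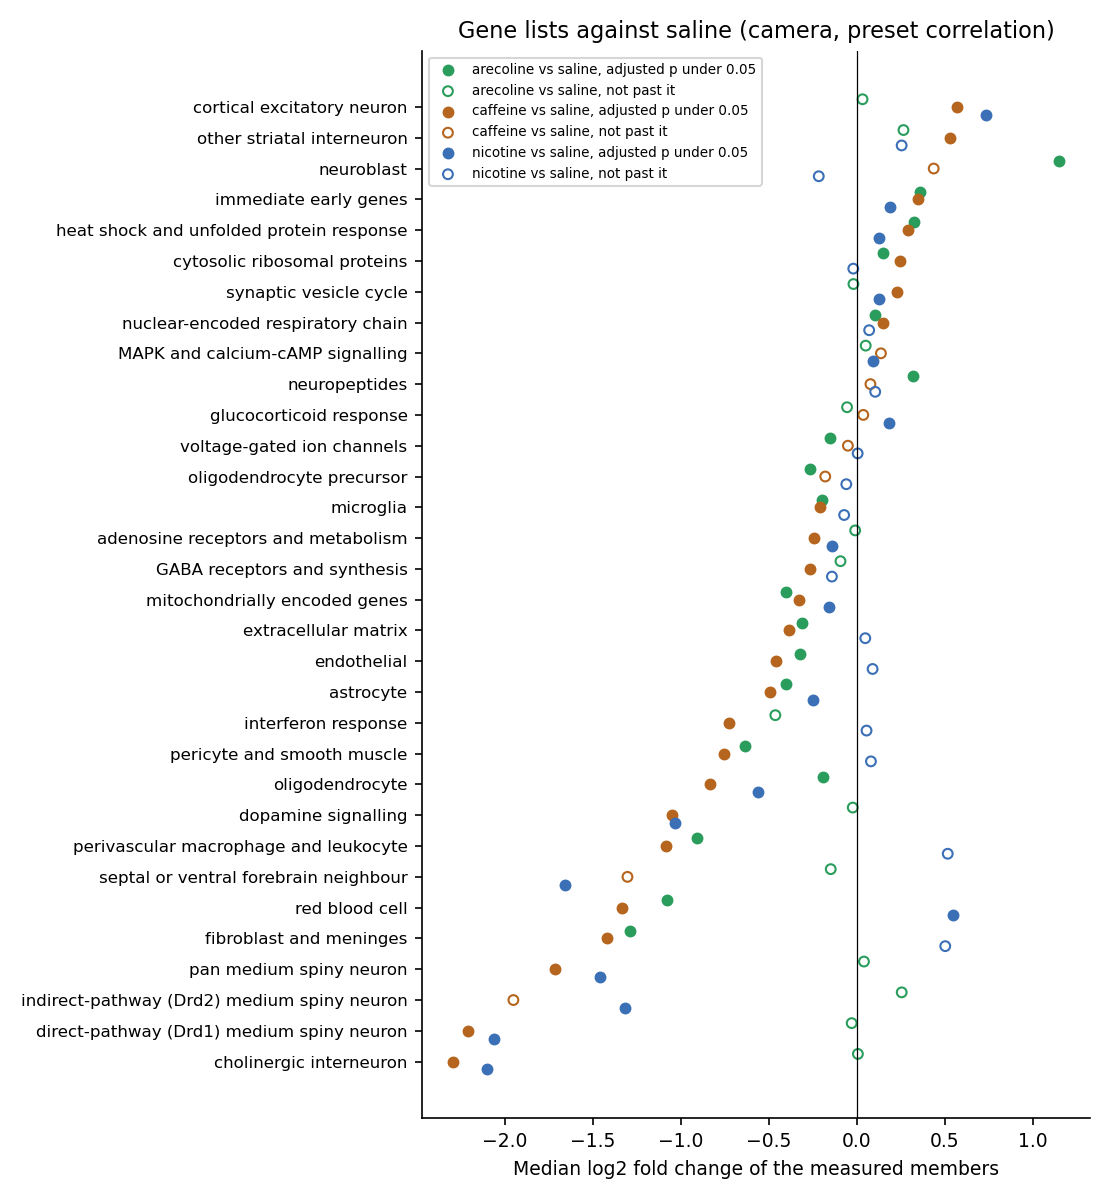
Median log2 fold change of each gene list that passed in at least 1 comparison with saline. Filled points had an adjusted p under 0.05 with camera at a preset correlation of 0.01 and open points did not. Oligodendrocyte genes lay at -0.83 with caffeine, -0.56 with nicotine and -0.19 with arecoline.

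Direct comparisons between compounds separated arecoline from nicotine in 13 genes, 3 higher and 10 lower with arecoline. Dlx5 (chromosome 6, 6877805 to 6882085), a transcription factor gene of forebrain GABAergic neurons, was at 29.1 CPM with arecoline and 6.82 CPM with nicotine (n = 4), a log2 difference of 2.09 ± 0.23 (SE; edgeR, adjusted p = 0.0013). Hs3st5 and the secretogranin gene Scg2 were also higher with arecoline, by 1.06 ± 0.19 and 0.91 ± 0.16. Clcn2 (-1.33 ± 0.17), the kinase gene Lats2 (-1.23 ± 0.20), the adenylyl cyclase gene Adcy9 (-0.95 ± 0.15), Plpp6 (-0.94 ± 0.16) and Pacs1 (-0.94 ± 0.15) were lower. Neuroblast genes ranked higher with arecoline by a median of 1.45, with 0 of 11 past the threshold over all genes and 9 when adjusted over the list alone (camera, adjusted p = 2.8e-08; with an estimated correlation, adjusted p = 0.583), and without arecoline replicate 1 the median was 0.96. Red blood cell genes ranked lower by a median of -1.61, with 0 of 6 over all genes and 4 when adjusted over the list alone (camera, adjusted p = 2.7e-05; with an estimated correlation, adjusted p = 0.583). The count of 13 became 2 without arecoline replicate 1 or 3 or nicotine replicate 2 or 3, 6 without nicotine replicate 1, 72 without nicotine replicate 4 and 298 without arecoline replicate 2, and it was 606 with DESeq2, 193 with the covariate and 282 without the 4 libraries that stood apart. Quantile normalisation of FPKM called 127 genes, of which 34.6% were higher against 23.1% of the 13.

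Between arecoline and caffeine, and between caffeine and nicotine, edgeR called 0 genes. For arecoline against caffeine 2325 genes had an unadjusted p under 0.05, DESeq2 called 370 and limma on FPKM called 0. The smallest p values there belonged to Dlx5 (log2 difference 1.35 ± 0.22), Tshz1 (1.82 ± 0.33), Btaf1 (0.93 ± 0.15), Mccc1 (0.61 ± 0.11) and Zfp386 (0.54 ± 0.11), higher with arecoline, and to Chrd (-1.39 ± 0.24), Clcn2 (-0.95 ± 0.17), Arhgap39 (-0.82 ± 0.15), Slc6a17 (-0.70 ± 0.12) and Slco3a1 (-0.68 ± 0.11), lower with it, and none passed. Oligodendrocyte genes were 1.54-fold higher with arecoline at the median, with 0 of 16 past the threshold over all genes and 16 when adjusted over the list alone (camera, adjusted p = 7.1e-13; with an estimated correlation, adjusted p = 0.858). Striatal lists had medians of 1.22 for dopamine signalling, 2.48 for direct-pathway, 1.41 for pan medium spiny and 2.13 for cholinergic neurons in the same contrast (camera, adjusted p from 2.7e-05 to 0.035; with an estimated correlation, adjusted p = 0.858 for each). Over all genes 0 of their members passed, and adjusted over the list alone 10, 6, 4 and 3 were higher and 1 direct-pathway gene was lower. Without the 4 libraries that stood apart these medians became -0.42, -0.13, -0.63 and -0.78, and that of oligodendrocyte genes went from 0.62 to 0.26. For caffeine against nicotine 1365 genes had an unadjusted p under 0.05, DESeq2 called 5 and limma on FPKM called 0. The smallest p values belonged to Nuf2 (1.90 ± 0.38), the kainate receptor gene Grik3 (0.66 ± 0.13), Prr3 (0.48 ± 0.12), Ppm1g (0.41 ± 0.10) and Erp29 (0.32 ± 0.08), higher with caffeine, and to Hbb-bt (-2.21 ± 0.46), Hba-a2 (-2.08 ± 0.43), Hba-a1 (-1.89 ± 0.41), Efcab7 (-1.65 ± 0.36) and Ifit3b (-1.34 ± 0.29), lower with it, and none passed. Ribosomal protein genes were higher with caffeine than with nicotine by a median of 0.27 on the log2 scale, in 50 of 50 cases but with 0 past the threshold on either count (camera, adjusted p = 5.6e-24; with an estimated correlation, adjusted p = 0.517). Of the 19 lists past the threshold here, that of fibroblasts and meninges had a median of -1.98 and that of extracellular matrix one of -0.25. Without nicotine replicate 2 these turned to 0.13 and 0.075. The count between arecoline and caffeine became 1, 67 and 3 without arecoline replicates 1, 2 and 4, and it was 86 without the 4 libraries that stood apart, where the count between caffeine and nicotine stayed at 0.

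The genes that changed with caffeine were not shown to respond to caffeine alone. For Trf the log2 difference between caffeine and nicotine was -0.22 with a 95% interval from -0.56 to 0.11, and for Dnajb1 it was 0.25 with an interval from 0.07 to 0.44 (edgeR, adjusted p = 0.666 and 0.493). Between arecoline and caffeine the difference in Trf was 0.73 with an interval from 0.39 to 1.07, and in Dnajb1 it was -0.27 with an interval from -0.45 to -0.09 (adjusted p = 0.109 and 0.167). For Drd1 the interval between caffeine and nicotine ran from -1.92 to 1.74. Both genes called with arecoline were also called higher with caffeine. Independent lists would share 0.04 genes, but these comparisons share their saline libraries, so the overlap does not show a shared effect. Across the 14674 genes, which are not independent replicates, log2 fold changes against saline correlated at r = 0.675 between arecoline and caffeine, 0.471 between arecoline and nicotine and 0.754 between caffeine and nicotine. Unchanged groups were simulated by shuffling the deviations of all libraries from their group means. The control they shared was thus drawn anew each time and was not the real saline group. These simulations gave means of 0.492, 0.490 and 0.498, with 95% ranges of 0.06 to 0.79, 0.05 to 0.79 and 0.06 to 0.81 that hold all 3 observed values. The covariance was 0.155, 0.084 and 0.165, against simulated 95% ranges of 0.0058 to 0.147, 0.0040 to 0.146 and 0.0057 to 0.143, so that of arecoline and nicotine lay inside its range and those of the other pairs lay above theirs. With the saline libraries split so that each compound had its own 2, the mean correlation fell to 0.368, 0.145 and 0.413 over 6 splits. Single splits ran from 0.19 to 0.51, from -0.07 to 0.36 and from 0.33 to 0.50. The splits reuse the same libraries, and no unchanged groups were simulated for them, so they do not decide on a shared effect.

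**Figure D4:**
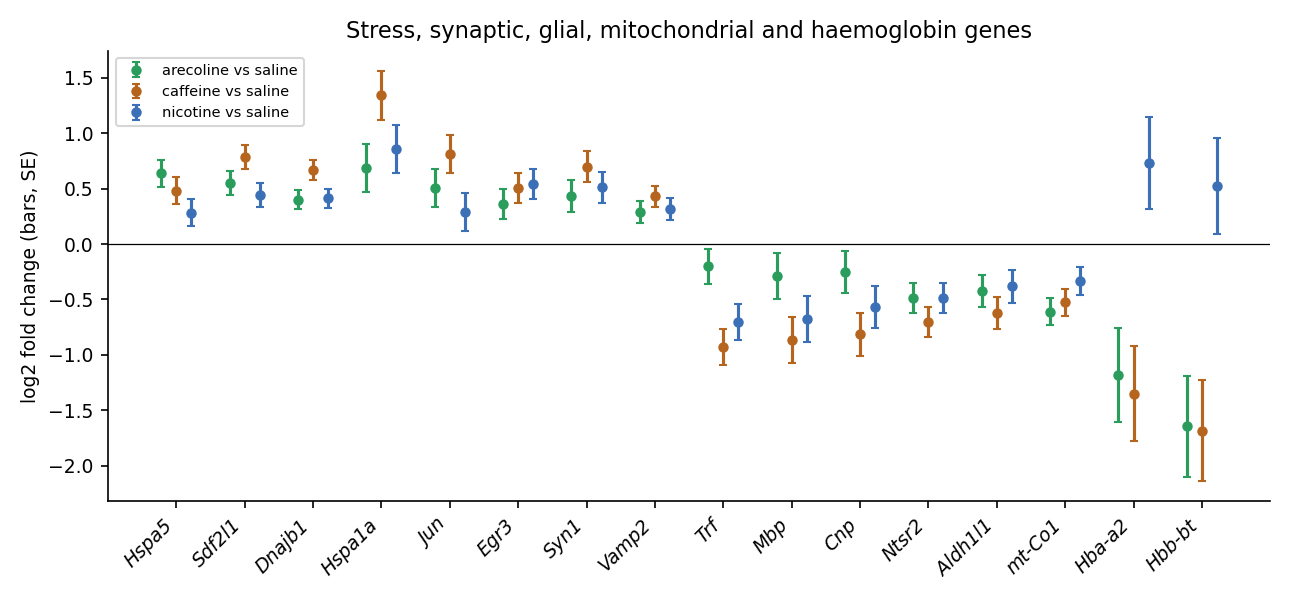
Log2 fold change against saline of 16 genes from the chaperone, early response, synaptic vesicle, oligodendrocyte, astrocyte, mitochondrial and red blood cell lists, with the standard error as bars and 4 libraries per group. Dnajb1 lay at 0.67 with caffeine, 0.41 with nicotine and 0.40 with arecoline, and the haemoglobin gene Hba-a2 lay at -1.35 with caffeine and 0.73 with nicotine.

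An F test over all 4 groups found 167 genes with a difference, of which 117 were also called between caffeine and saline, 13 between arecoline and nicotine and 2 between arecoline and saline. In none of the 6 contrasts were 37 of them called. This count became 1 without caffeine replicate 1 or 2, 3 without saline replicate 2, 21 without arecoline replicate 1 or nicotine replicate 3, 32 without nicotine replicate 1, 42 without nicotine replicate 4, 62 and 76 without caffeine replicates 4 and 3, 86 and 92 without saline replicates 1 and 4, 97 without arecoline replicate 3 and 351 without arecoline replicate 2. It was 1194 without the 4 libraries that stood apart, 154 of them shared.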

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

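Some libraries stood far from the other 3 of their group, by a rule fixed for 172 measures in each of 4 groups, the gap from the next library against the range. It named 44 of 688 combinations, against 34.4 by chance at the 5% level, so most could be chance. Saline replicate 3 held 15 of them. Its scores, means of centred log2 levels, were 1.57 for dopamine signalling, 1.78 for direct-pathway neurons, 2.13 for pan medium spiny neurons, 2.52 for cholinergic interneurons, -1.72 for cortical excitatory neurons and -0.24 for mitochondrially encoded genes. Its log2 CPM values were 8.26 for Drd1, 4.61 for Chat, 4.49 for Slc5a7, 11.19 for Penk, 4.44 for Dlx5, 4.71 for Tshz1, 6.80 for Chrnb2, 6.82 for Junb and 5.83 for Slc17a7. Caffeine replicate 4 had scores of 0.0478 for dopamine signalling, 0.13 for direct-pathway, 0.24 for indirect-pathway and 0.13 for pan medium spiny neurons, with log2 CPM of 5.16 for Adora2a, 6.91 for Tac1 and 5.33 for Chrd. Nicotine replicate 2 had scores of 3.08 for fibroblasts and meninges and 0.23 for oligodendrocyte precursors, with 8.26 for Acsbg1 and -0.0251 for Tex47.

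The other libraries named by the rule carried 1 to 3 genes each. In log2 CPM, saline replicate 2 had 1.305 for Npy2r, 6.24 for Rtn4rl1 and 4.75 for Zfp386, and saline replicate 4 had 3.20 for Egr4. Among arecoline libraries, replicate 1 had 2.21 for Cdh18 and -1.62 for Tnfrsf25, replicate 3 had 3.67 for Cramp1l and 2.73 for Npas4, and replicate 4 had 5.43 for F8a. Among caffeine libraries, replicate 1 had 4.66 for Sdf2l1 and 12.22 for mt-Nd1, replicate 2 had -0.28 for Cyp2j12 and replicate 3 had 3.05 for Hs3st5. Among nicotine libraries, replicate 1 had 2.39 for Cfap45 and 7.76 for Ddn, replicate 3 had 8.06 for Camkk2 and 8.01 for Lamp5, and replicate 4 had 2.86 for Prr18. No cause was tested for these.

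Medium spiny neuron genes moved against cortical genes between libraries of the same group, in tests chosen after seeing the data. Within groups the pan medium spiny neuron score correlated with the cortical excitatory neuron score at r = -0.81 over 16 libraries (permutation p = 0.0032, rho = -0.88 with permutation p = 0.0057, r = -0.71 without the 2 farthest libraries, adjusted p = 0.0065 over 2 relations). With the oligodendrocyte score it correlated at r = 0.70 (permutation p = 0.0077, rho = 0.64 with permutation p = 0.017, r = 0.60 without the 2 farthest libraries, adjusted p = 0.0077), so oligodendrocyte genes moved with striatal genes where the exposure was the same. A hypothesis is that the dissected pieces held different shares of striatum and cortex, and this relation is consistent with it. A response of these neurons to caffeine was neither shown nor excluded, since the exact permutation p of 0.029 for the score against saline restates the lower scores already seen and was 0.145 when adjusted over 132 score tests. Arecoline replicate 1 had the lowest pan medium spiny neuron score of all libraries, -1.28, with a cortical score of -0.0057. The 4 measured genes of olfactory bulb projection neurons were highest there, so tissue other than cortex was not excluded. Counting striatal, cortical and olfactory bulb cells in sections of the same dissections would separate a difference in tissue from a response.

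Nicotine replicate 2 held genes of the nose. Several of the genes counted here, such as Cyp2g1, Ugt2a1 and Omp, led the principal component on which this library stood apart. The count therefore restates that pattern and is not independent of it. Of 17 olfactory epithelium genes, 13 were at 4 times the next library or more, in a test chosen after seeing the data. These included 6 of 8 sensory neuron genes and 7 of 9 supporting cell and gland genes, while 0 of 4 genes of olfactory bulb projection neurons did so. Caffeine replicate 1 had the next highest level of each of the 13, such as 16.6 against 205 CPM for Cyp2g1 by plain library total. All 7 supporting cell and gland genes that passed were among the 15 genes at this library's end of that component, so their passing restates it. Obp1a and Obp2a, the supporting cell and gland genes that did not pass, stood at 1.28 and 1.57 times the next library. The count therefore does not decide on sensory axons as the source. Axons, a piece of epithelium in the sample, or reads from another library of such tissue remained open.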

How the results depend on the processing

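Gene counts moved with the tool, the filter and single libraries, and the cause was not tested. Results follow with the main value first, and the covariate and the removal of 4 libraries were chosen after seeing the data. For arecoline and saline, 2 became 450 with DESeq2, 0 with only the 8 libraries of the 2 groups, 98 with the replicate block, on FPKM with limma 4 at a pseudocount of 0.1, 1 without a filter, 75 at FPKM of at least 5 and 207 with quality weights, then in edgeR 99 with the covariate, 952 without the 4 libraries, 803 at unadjusted p and 1.5-fold, and 0 to 198 without single libraries. For caffeine and saline, 599 became 1489 with DESeq2, 997 with the block, on FPKM with limma 285 without a filter and 1569 with weights (in edgeR without a filter 454), 126 with the covariate, 1491 without the 4 libraries, 356 at 1.5-fold, 1515 at unadjusted p and 1.5-fold, and 23 to 995 without single libraries. For nicotine and saline, 0 became 104 with DESeq2, 2 with the block, 16 on FPKM with limma and weights, 48 without the 4 libraries, 701 at unadjusted p and 1.5-fold, and 0 to 4 without single libraries. For arecoline and nicotine, 13 became 606 with DESeq2, 3 with only 8 libraries, 219 with the block, on FPKM with limma 56 and 50 at pseudocounts of 1 and 0.1, 2 without a filter, 159 at FPKM of at least 5, 49 with median ratio scaling, 127 with quantile scaling and 251 with weights, then in edgeR 193 with the covariate, 282 without the 4 libraries, 1174 at unadjusted p and 1.5-fold, and 2 to 298 without single libraries. For arecoline and caffeine, 0 became 370 with DESeq2, 37 with the block, 1 on FPKM with limma and weights, 5 with the covariate, 86 without the 4 libraries, 816 at unadjusted p and 1.5-fold, and 0 to 67 without single libraries. For caffeine and nicotine, 0 became 5 with DESeq2 and 533 at unadjusted p and 1.5-fold, and stayed 0 without single libraries. Over the 4 groups, 167 became 426 with the block, on FPKM with limma 88 and 96 at the 2 pseudocounts and 103 and 55 with median ratio and quantile scaling, then in edgeR 1194 without the 4 libraries, and 1 to 351 without single libraries. Replicate numbers paired libraries weakly at most. Of 24 same-number pairs 8 had r above 0.1, with a mean of 0.049 against -0.016 for other pairs. The number of libraries that correlated best with their own number was 6. Pairing was not tested, so the values do not settle whether the block is warranted. Lists past the threshold numbered 18, 24, 17, 16, 8 and 19 in the 6 contrasts, 0 in each with an estimated correlation, 1, 7, 0, 0, 0 and 0 with fry, 13 for caffeine with the covariate, 5 for arecoline and caffeine on FPKM with quantile scaling, and 12 to 21, 21 to 25, 13 to 22, 13 to 21, 5 to 13 and 11 to 18 without single libraries. Split controls took the correlations of 0.68, 0.47 and 0.75 to 0.37, 0.14 and 0.41. The covariate is the mean of the pan medium spiny neuron genes, so it takes that list to near 0 by construction. Some of these genes are also dopamine signalling genes, which ties that list to the covariate in part. Directions turned with it for medians of dopamine (0.0399) and pan medium spiny neuron genes (0.10), Chrm4 (0.40) and Penk (0.18) with caffeine, adenosine (0.0216) and indirect-pathway lists (0.37), Adora2a (0.68), Drd2 (0.57) and Penk (0.43) with nicotine, and cholinergic genes between arecoline and caffeine (-0.12). Without the 4 libraries they turned between arecoline and nicotine for dopamine (-0.61), indirect-pathway (-1.14), pan medium spiny neuron (-0.79) and oligodendrocyte lists (-0.0407), between arecoline and caffeine for dopamine (-0.42), direct-pathway (-0.13), pan medium spiny neuron (-0.63) and cholinergic lists (-0.78), and between caffeine and nicotine for matrix (0.0773) and fibroblast lists (0.14). The septal list with nicotine turned on FPKM with limma (0.23), also with median ratio (0.24) and quantile scaling (0.26), and quantile scaling of FPKM also turned mt-Co3 with caffeine (0.0639) and respiratory genes between caffeine and nicotine (-0.00236). Without single libraries the fibroblast median ran from -2.30 to 0.31 between arecoline and nicotine and from -2.35 to 0.13 between caffeine and nicotine, and the matrix median from -0.31 to 0.0750 in the latter, each turning without nicotine replicate 2.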

Other observations

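Chaperone genes ranked higher in each comparison with saline, at median log2 fold changes of 0.33 with arecoline, 0.29 with caffeine and 0.13 with nicotine (camera, adjusted p = 1.1e-08, 4.8e-08 and 0.0052; with an estimated correlation, adjusted p = 0.380, 0.422 and 0.441). The 3 comparisons share the same saline libraries, so their likeness is not evidence of a common response. Oligodendrocyte medians were -0.19, -0.83 and -0.56. Their difference between arecoline and caffeine had an adjusted p of 0.858 with an estimated correlation, and that between arecoline and nicotine went from 0.42 to -0.0407 without the 4 libraries that stood apart, an alternative chosen after seeing the data. Red blood cell medians were -1.08, -1.34 and 0.55, with an exact permutation p of 0.2 for the score of nicotine against saline, and no haemoglobin gene passed between caffeine and nicotine.

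The 599 genes called between caffeine and saline were weighed against 3 technical explanations, by alternatives chosen after seeing the data. With the medium spiny neuron score as a covariate, the median ratio of log2 fold change to that before was 0.88 (quartiles 0.74 to 0.99), and 92 of the 599 genes were still called, so a difference in the tissue sampled may contribute and was not excluded. Thinning all libraries to 9.04 M counts gave a ratio of 0.997 (quartiles 0.96 to 1.03), and removing trends on transcript length, GC content and gene span gave 0.964 (quartiles 0.89 to 1.01). The latter argues against these gene properties as the main source. Thinning leaves each gene's expected share of its library unchanged, so its ratio was bound to move little and does not decide on depth. After thinning, 473 of the 599 genes were still called. Dissections with the striatal share measured per sample would test the tissue explanation.

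Chance assignment of libraries was tested by every split of the same 8 libraries into 4 and 4, 35 per comparison, counting those with as many genes as the real one. For caffeine and saline 1 of 35 reached 599, the real one, with 0 genes in any other, and for arecoline and nicotine 1 of 35 reached 13, again with 0 in any other. For arecoline and saline 7 of 35 reached 2, and the highest, 679, put saline replicates 1 and 3 with arecoline replicates 2 and 3, so it may reflect the tissue pattern. The real count was 0 for nicotine and saline, for arecoline and caffeine and for caffeine and nicotine. Any split reaches 0, so the 35 of 35 found there were fixed in advance and say nothing about chance. Over the 4 groups, 2 of 100 drawn assignments reached 167, the other at 853.

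List counts were put to the same splits. As many lists passed in 5 of 35 splits for arecoline and saline (18 lists), 1 for caffeine and saline (24 lists, at most 21 in another), 11 for nicotine and saline (17 lists), 19 for arecoline and nicotine (16 lists), 20 for arecoline and caffeine (8 lists) and 3 for caffeine and nicotine (19 lists). The median of the other splits ran from 8.5 to 16 lists, so camera at its preset correlation could call many lists in groups that differ by chance alone, and 0 passed in any comparison with an estimated correlation.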
